A study of Mus musculus with 6 samples.

How the data were processed

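Total RNA was extracted with TRIzol from first molars of WT and Gpr115-KO littermates of the C57BL/6 strain, and libraries were made with a Nextera XT kit and sequenced on a HiSeq1500 as paired reads of 150 nt, per the labels' protocols. The kit fragments complementary DNA with a transposase and does not mark strand, so reads from stretches that genes on opposite strands share cannot be told apart. Each group held 3 libraries, numbered 1 to 3 in the labels. The labels do not say whether each library came from 1 animal or from pooled germs, so p-values measure the spread between these libraries.

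The submitters' processing notes name STAR 2.5.2a, DESeq2, edgeR and limma, and the mouse build GRCm38 (mm10). The counting tool and the annotation release are not given in the sources used here. The authors deposited raw counts per gene, with 48709 gene rows and 15 rows for transgene sequences that together took at most 8 counts in any library. The transgene rows were kept out of library sizes and tests. The deposited normalized table holds a signal that is CPM scaled by TMM, as the file name and the values show. Its 20162 rows, when each column was divided by 1 factor, gave whole reads for 100% of values (tolerance 0.01 reads), all equal to the deposited counts. Its columns sum to 937403 to 1085499, so it is not plain CPM. Every row it leaves out had at most 5 counts in any library. Library totals ran from 8317308 to 11122826 counts.

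Gene symbols came from the deposited normalized table and otherwise from GENCODE vM21, the annotation of the same build. Of the gene rows 360 had no entry there, 38 of them among the tested genes. Coordinates, strands, overlaps and exonic lengths are from that annotation.

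Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes passing filterByExpr (minimum count 10, minimum total 15) were kept, 16011 in all. Libraries were scaled by TMM, and genotype was the only term of a robust quasi-likelihood fit with a two-sided F test. P-values were adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 was called. The standard error is the absolute log2 fold change divided by the square root of F. CPM are counts divided by the TMM-scaled library size and given per 1e6, and no pseudocount entered the CPM printed. The biological coefficient of variation was 23.1%.

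The test was tried on simulated data for the same comparison, with the means and library sizes of the real libraries, 16011 genes and 200 of them changed. It recovered 43.9% of the genes changed by 1 on the log2 scale and 92.8% of those changed by 2, and 14 of 147 calls were false (9.52%). A simulated list shifted upward had a camera p of 7.8e-16, and 3 of 100 random lists had a p under 0.05. Each gene was simulated independently, so this does not show how camera behaves for lists with correlated members. Among the real lists the estimated correlation was 0.51 for the erythroid and 0.20 for the leukocyte list.

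The 24 gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except for those named here and in the closing section as added. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated one, and with fry, adjusted over the 24 lists. A member was measured if it passed the count filter. Genes were named by a rule in 3 parts. The first names Adgrf4, Car6, Amelx, Ambn, Enam, Mmp20, Klk4, Amtn, Odam and Dspp whatever their values. The second names, in each direction, up to 12 genes of the largest fold change with an adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap between the genotypes' libraries, without predicted genes, pseudogenes or genes with no symbol. It gave 6 higher and 9 lower genes, so the provision that fills a direction up to 5 was not needed. The third names up to 4 called members of each list, or the 2 with the smallest p where none was called. The rule named 67 genes, of which some are not reported here.

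Before averaging, all pairs of libraries were compared by a chi-square of their counts. The statistic per degree of freedom was 16.1 to 67.5 for pairs of 1 group and 15.6 to 87.4 for pairs across groups, far above the level near 1 of a repeated sampling of the same library. Near-identical copies were found by blastn 2.17.0 between transcripts of GENCODE vM21, at 95% identity over at least 150 nt.

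Alternatives were DESeq2 size factors in edgeR, library totals alone, no count filter, at least 10 counts in every library, the DESeq2 1.42.0 Wald test, limma-voom, no robust shrinkage, the replicate number as a block, limma-trend on log2 of the deposited values plus 1, other thresholds, and each library left out in turn. Added after the data were seen were chromosome 17 left out, edgeR on the reads recovered from the deposited normalized table, 2 lists without their chromosome 17 members, the trend of each library on exonic gene length removed as an offset, and list tests with an estimated correlation and each library left out. Of the tested genes 38 had no length and were left uncorrected. The deposited columns were all assigned to a library, and 0 were left over.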

Results

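RNA was sequenced from first molar tooth germs of mice at postnatal day 7, an age at which the enamel epithelium passes from secreting enamel matrix to maturing it. Gpr115, listed in the deposited tables under its current symbol Adgrf4, encodes an adhesion G protein-coupled receptor. The study asked which transcripts of the tooth germ differ when this receptor is missing. There were 3 wild-type (WT) libraries and 3 libraries from Gpr115-deficient littermates (Gpr115-KO). The WT libraries held 11122826, 8833616 and 10642517 counts and the Gpr115-KO libraries 8317308, 9710473 and 10328656. Ambn, which encodes the enamel matrix protein ameloblastin, took 7.30% to 13.5% of the counts in 5 libraries. In Gpr115-KO replicate 3 the highest share belonged to Col1a1, a collagen gene of dentin and bone, with 6.15%. A single count was worth 0.0907 to 0.114 CPM, and a count of 0 in 1 library allowed levels up to 0.272 to 0.342 CPM, counting error only.

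The targeted gene was examined first. Adgrf4 (ENSMUSG00000023918; chromosome 17, 42656891 to 42692284 on GRCm38, minus strand) was lower in each Gpr115-KO library than in any WT library. Its normalised read count was 65.7 ± 2.77 CPM in WT (SD, n = 3) and 29.1 ± 9.39 CPM in Gpr115-KO (SD, n = 3), so the Gpr115-KO mean was 44.3% of the WT mean. Single libraries read 67.1, 62.5 and 67.5 CPM in WT and 39.2, 20.6 and 27.5 CPM in Gpr115-KO. The log2 fold change was −1.18 (SE 0.21). In edgeR's quasi-likelihood test the adjusted p was 0.0887, so the difference did not pass the 0.05 threshold over all 16011 genes tested. It passed without Gpr115-KO replicate 1, with a log2 fold change of −1.45 (edgeR adjusted p = 0.0143), and the adjusted p ran from 7.4e-07 to 0.325 over its 16 alternatives. The part of the gene that was deleted is not given in the labels, so reads from the remaining exons cannot be separated from reads of an intact transcript.

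Car6 encodes a secreted carbonic anhydrase. It was named before the data were examined because it was tied to Gpr115 in what was known of this study, so the choice was not independent of the study. Car6 (ENSMUSG00000028972; chromosome 4, 150187015 to 150201332) had 154, 77.9 and 113 CPM in the WT libraries. The Gpr115-KO libraries were split: replicate 1 had 113 CPM, within the WT range, and replicates 2 and 3 had 7.48 and 12.3 CPM. The log2 fold change was −1.39 (SE 1.15, edgeR adjusted p = 0.689), smaller than the spread between replicates allows to be called. Without Gpr115-KO replicate 1 it was −3.53 (edgeR adjusted p = 0.00578), and the adjusted p ran up to 0.947 over its 16 alternatives.

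The enamel matrix genes showed no difference beyond the replicate spread. Amelx, encoding amelogenin, had a log2 fold change of 0.52 (SE 0.30). That of Ambn was 0.08 (SE 0.36), that of Enam, encoding enamelin, −0.14 (SE 0.26), and that of Mmp20, the protease of secretory-stage enamel, 0.39 (SE 0.23). Genes of the maturation stage were likewise not past the threshold. Klk4, the protease that clears the enamel matrix, had −0.24 (SE 0.28), Amtn, encoding amelotin, 0.04 (SE 0.19), and Odam, encoding an adhesion protein of maturing ameloblasts, −0.29 (SE 0.49). Odam was spread widely in Gpr115-KO, with 7942, 1473 and 4583 CPM in replicates 1 to 3, against 5701 ± 26.0 CPM in WT (SD, n = 3). Dspp, encoding the main dentin phosphoprotein precursor, had 0.16 (SE 0.40). The edgeR adjusted p-values of these 8 genes lay between 0.510 and 0.947.

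**Figure D1:**
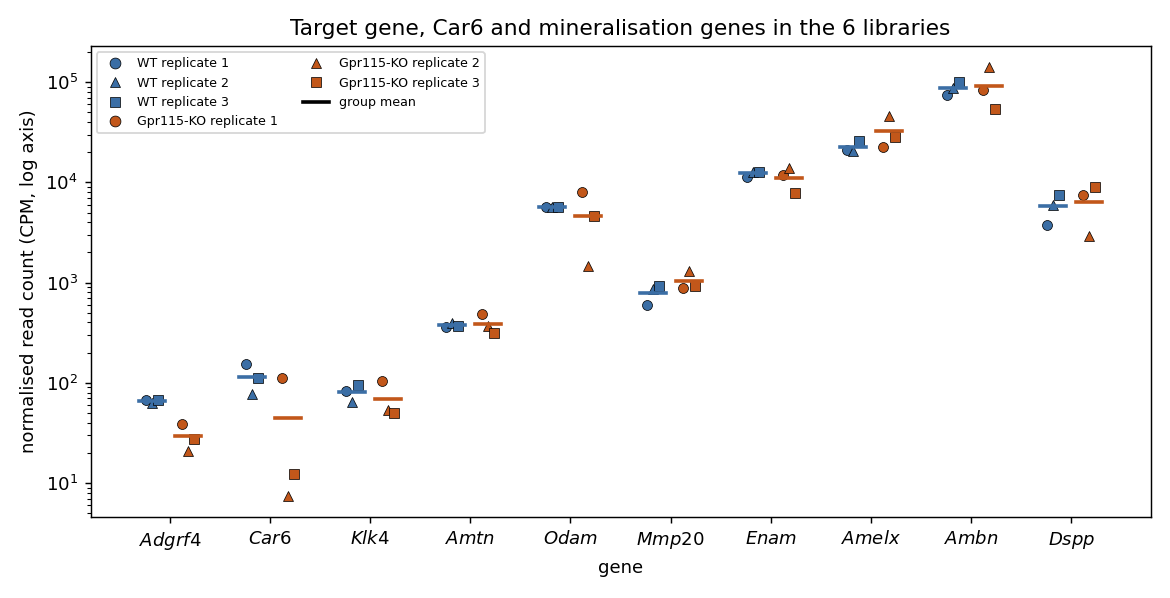
Normalised read counts (CPM, log axis) of Adgrf4, Car6, 7 enamel genes and Dspp in each library, with WT in blue, Gpr115-KO in orange, replicates by marker shape and group means as bars. Adgrf4 lay at 62.5 CPM or above in WT and at 39.2 CPM or below in Gpr115-KO, while Car6 in Gpr115-KO replicate 1, at 113 CPM, lay within the WT range.

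Over all genes, 6 were higher and 18 were lower in Gpr115-KO at an adjusted p under 0.05. The libraries of both genotypes did not overlap in any of these 24 genes. Of all tested genes 17.5% had non-overlapping libraries, where chance gives 10%. At an unadjusted p under 0.05 there were 1975 genes, of which 777 were higher and 1198 lower, against 800.55 expected by chance. DESeq2 called 60 higher and 177 lower. Leaving out WT replicate 1, WT replicate 2 or Gpr115-KO replicate 1 gave 9, 7 and 39 lower genes, and leaving out WT replicate 2 gave 10 higher genes.

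Of the 24 called genes, 18 lay on chromosome 17, the chromosome of Adgrf4, which held 724 of the 16011 genes tested. The number expected there was 1.09 (two-sided Fisher's exact test across genes, p = 5.3e-20; genes are not independent replicates). All 6 higher genes and 12 of the 18 lower genes were on this chromosome. They spread over 43.4 Mb, from 24404649 to 67822647, and 10 of the 18 began between 30 and 40 Mb, a stretch that holds the major histocompatibility complex. Of the 724 tested genes of the chromosome 172 began in that stretch. The called gene nearest to Adgrf4 began 2.87 Mb away. In an alternative added after the data were seen, chromosome 17 was left out and the same edgeR p-values were adjusted anew. It left 0 higher and 2 lower called genes, Gm10260 and Rps2-ps10.

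The largest increase was in Tmem151b, which encodes a transmembrane protein, at 0.567 ± 0.159 CPM in WT and 39.9 ± 22.1 CPM in Gpr115-KO (SD, n = 3). Its log2 fold change was 6.09 (SE 0.49, edgeR adjusted p = 0.000827). The adjacent Tcte1, a testis-expressed gene, had a log2 fold change of 4.79 (SE 0.58, edgeR adjusted p = 0.0121), from WT counts of 7, 1 and 7. The genes overlap at their ends on opposite strands, and the library kit does not mark strand, so reads from the shared stretch cannot be told apart. The class Ib histocompatibility genes H2-T23 and H2-T24 rose by 2.63 (SE 0.23) and 2.41 (SE 0.22) on the log2 scale. Prrc2a, encoding a proline-rich coiled-coil protein, rose by 1.93 (SE 0.22), and Atp6v0e, encoding a subunit of the vacuolar proton pump, rose by 1.29 (SE 0.17), from 146 ± 12.4 to 357 ± 48.6 CPM (SD, n = 3). The edgeR adjusted p-values of these 4 genes were 0.000827, 0.000827, 0.00442 and 0.0126. H2-T23 has near-identical copies, and how reads shared between copies were counted is not given in the sources used here. The call of Atp6v0e was lost without WT replicate 1, 2 or 3 (edgeR adjusted p = 0.103, 0.126 and 0.0559), and that of Tcte1 without WT replicate 1 or 3 (0.104 and 0.0602) and with limma-voom (0.121).

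Among the lower genes, BC023719 had WT counts of 94, 100 and 159 and Gpr115-KO counts of 2, 2 and 3, a log2 fold change of −5.57 (SE 0.42, edgeR adjusted p = 0.000656). It overlaps the histocompatibility pseudogene H2-T10 (−4.91) on the opposite strand, and both have near-identical copies. Luc7l, encoding a splicing-related protein, went from 942 ± 108 to 69.7 ± 28.6 CPM (SD, n = 3), a log2 fold change of −3.76 (SE 0.29). Cramp1l, encoding a chromatin protein, went from 224 ± 51.0 to 8.22 ± 4.04 CPM (SD, n = 3), a log2 fold change of −4.78 (SE 0.38). The edgeR adjusted p-values were 0.000656 for Luc7l and 0.000946 for Cramp1l. Smaller decreases were called in Nrm (−1.83, a nuclear envelope protein), Lama1 (−1.73, a laminin chain of basement membranes), Sapcd1 (−1.61), Vwa7 (−1.60) and the class I histocompatibility gene H2-D1 (−1.11). Sapcd1 and Vwa7 overlap on opposite strands, Nrm overlaps an antisense transcript, and H2-D1 has near-identical copies. Lama1 (edgeR adjusted p = 0.0274) and H2-D1 (0.0401) lost their calls when any library but WT replicate 3 was left out, with an adjusted p of 0.0611 to 0.154 for Lama1 and 0.0537 to 0.18 for H2-D1. They also lost them on library totals alone (0.0858 and 0.0886) and with limma-voom (0.0860 and 0.0692), and H2-D1 in edgeR without robust shrinkage (0.0555). Without WT replicate 1 or 2 the calls of Nrm (0.0587 and 0.0685), Sapcd1 (0.0791 and 0.0802) and Vwa7 (0.0604 and 0.0667) were lost too.

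**Figure D2:**
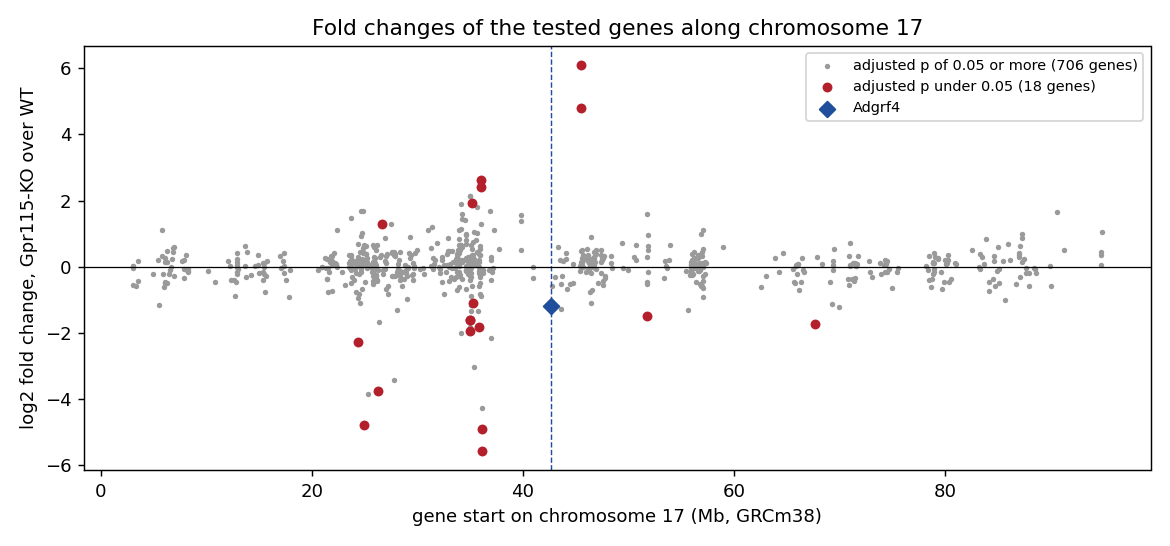
Log2 fold change of each tested gene (Gpr115-KO over WT) against its start on chromosome 17 in Mb (GRCm38), with the 18 genes at an adjusted p under 0.05 in red and Adgrf4 as a blue diamond on a dashed line. The called genes spread over 43.4 Mb on both sides of Adgrf4, with 10 of them between 30 and 40 Mb, where 172 of the 724 tested genes began.

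The other 6 called genes were all lower. Ube4bos1, an antisense transcript of Ube4b on chromosome 4 (149347885 to 149365277), had a log2 fold change of −1.85 (SE 0.27, edgeR adjusted p = 0.0274). This call was lost whichever library was left out (edgeR adjusted p 0.0584 to 0.152), on library totals alone (0.0565) and with limma-voom (0.0700). The rest fall outside the rule for named genes and were looked up after their values were seen. Rps2-ps10 on chromosome 18 had a log2 fold change of −3.12, Gm10260, Gm26619 and Gm10263 on chromosome 13 had −2.40, −2.31 and −3.12, and Gm43413 on chromosome 5 had −1.32. All but Gm43413 and Ube4bos1 resemble a ribosomal protein gene within the called stretch of chromosome 17 at 95% identity or more over at least 150 nt.

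Of the 4 main gene lists fixed before the data were examined, none passed the competitive test (camera, adjusted over 24 lists), and none of their members passed over all genes tested or adjusted over the list alone. Of 17 measured secretory ameloblast genes 13 had a fitted fold change above 0 (median log2 0.13, adjusted p = 0.162). Fam83h and Sp6, both tied to enamel formation, had the smallest p, with log2 fold changes of 0.94 (SE 0.27) and 0.64 (SE 0.22). This list passed, upward, without WT replicate 3 (adjusted p = 0.0481, and 0.998 with an estimated correlation) and without Gpr115-KO replicate 3 (adjusted p = 0.0157, estimated 0.745). Of 20 measured maturation ameloblast genes 13 lay below 0 (median −0.17, adjusted p = 0.264), among them the calcium sensor Stim1 (−0.59, SE 0.20) and the transferrin receptor Tfrc (−0.32, SE 0.20). Without Gpr115-KO replicate 1 this list passed, downward, at an adjusted p of 6.4e-06 (0.149 with an estimated correlation). The 8 measured carbonic anhydrases had a median of 0.14 (adjusted p = 0.845), with Car14 at 0.50 (SE 0.39) and Car1 at 1.04 (SE 0.80). The 20 measured odontoblast genes had a median of 0.15 (adjusted p = 0.658), with Wnt10a at 0.51 (SE 0.19) and Runx2 at −0.52 (SE 0.20), and passed, upward, without Gpr115-KO replicate 2 (adjusted p = 0.00594, and 0.986 with an estimated correlation).

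Markers of blood cells were higher in Gpr115-KO by the competitive test at its preset correlation, and not by the self-contained test (fry adjusted p = 0.250 for both lists, and 0.159 and 0.0929 for change in either direction). All 7 measured erythroid genes lay above 0, with a median log2 fold change of 1.22 (camera adjusted p = 5.7e-07, and 0.498 with an estimated correlation between members). None passed over all genes tested and 6 of 7 passed adjusted over the list alone. The median of the list was 7.44, 6.48 and 7.32 CPM in WT and 17.8, 24.9 and 8.96 CPM in Gpr115-KO. In Gpr115-KO replicate 3 the globin genes Hbb-bs, at 54.2 CPM, and Hba-a1, at 78.5 CPM, lay within the WT ranges. The beta-globin gene Hbb-bt had 7.08 ± 0.522 CPM in WT and 19.5 ± 10.4 CPM in Gpr115-KO (SD, n = 3). The anion exchanger of red cells, Slc4a1, had a log2 fold change of 1.47 (SE 0.36). Of 17 leukocyte genes 15 lay above 0, with a median of 0.42 (camera adjusted p = 3.7e-05, and 0.498 with an estimated correlation). None passed over all genes and 7 of 17 passed adjusted over the list alone. These included the neutrophil granule gene Mpo (1.5, SE 0.33) and S100a9 (1.81, SE 0.48), while the monocyte receptor gene Csf1r stood at −0.13 (SE 0.18). Without its chromosome 17 members the leukocyte list had an adjusted p of 6.4e-05.

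Single libraries stood apart in markers of neighbouring tissue and of sex. The 11 skeletal muscle genes had a median log2 fold change of 1.09 (adjusted p = 0.154), and the median of the list was 28.0 CPM in Gpr115-KO replicate 2 against 2.51 to 5.98 CPM in the other libraries. Mylpf and Tnni2, encoding muscle contractile proteins, had 1.48 (SE 0.71) and 1.04 (SE 0.67). The 14 keratinizing oral epithelium genes had a median of 0.11 (adjusted p = 0.976), with Dmkn at 0.29 (SE 0.43) and Krt10 at 0.14 (SE 0.21). The list's median was 9.57, 1.02 and 8.13 CPM in WT and 14.6, 1.82 and 1.10 CPM in Gpr115-KO. Xist, the RNA of the inactive X chromosome, had 2.93 CPM in Gpr115-KO replicate 3 and 28.9 to 47.8 CPM elsewhere. Its log2 fold change was −0.35 (SE 0.89) and that of the overlapping Tsix −0.23 (SE 0.59). These were the 2 measured members of the sex-linked list, which was not called (adjusted p = 0.699), and its 4 Y-linked genes did not pass the count filter and were not tested.

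The median fold change went from above 0 to below 0 with increasing gene length. Across 12859 protein-coding genes the log2 fold change fell with exonic length (Spearman's rho −0.29, across genes, which are not independent replicates). With the genes ranked by length into 5 groups of near-equal size, the median was 0.15 in the shortest group and −0.14 in the longest. The same rho for each library's deviation from the mean of all libraries was 0.25, 0.22 and −0.01 in WT and −0.01, −0.25 and −0.11 in Gpr115-KO. With this trend removed, edgeR called 8 higher and 19 lower genes, which included all 24 called without the correction. The median log2 fold change of the leukocyte list went from 0.42 to 0.22 and that of the erythroid list from 1.22 to 1.0.

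The remaining lists were not called. The vacuolar proton pump list had 1 member past the threshold, Atp6v0e, and 20 of 21 not past it (adjusted p = 0.162). It passed, upward, without Gpr115-KO replicate 3 (adjusted p = 0.0372, and 0.745 with an estimated correlation) and stood at 0.599 without its chromosome 17 members. A self-contained test of change in either direction (fry) on all 6 libraries had an adjusted p of 0.0282. The bicarbonate and proton transporters had a median of −0.09 (adjusted p = 0.976), with Slc26a2 at 0.29 (SE 0.16) and Slc4a1, also an erythroid gene, past the threshold adjusted over the list alone. Calcium handling had a median of 0.09 (adjusted p = 0.884; Trpm7 at −0.72, SE 0.25), and iron handling −0.06 (adjusted p = 0.922; Slc40a1 at 0.42, SE 0.18). General dental epithelium had a median of −0.10 (adjusted p = 0.230), with Cdh1, encoding E-cadherin, at −0.62 (SE 0.18) and Notch1 at −0.82 (SE 0.29). The claudin and tight junction list had −0.06 (adjusted p = 0.494), with Marveld2, encoding tricellulin, at −1.32 (SE 0.31), past the threshold adjusted over the list alone, and Tjp1 at −0.59 (SE 0.22). Without Gpr115-KO replicate 1 the dental epithelium list (adjusted p = 0.0101) and the keratinizing list (0.000935) passed downward and the skeletal muscle list (3.4e-07) upward. With an estimated correlation these calls were lost (adjusted p = 0.614, 0.614 and 0.515). The skeletal muscle list also passed, upward, without WT replicate 1 (adjusted p = 0.0131, estimated 0.945) and without Gpr115-KO replicate 3 (0.0441, estimated 0.802). Without Gpr115-KO replicate 2 its direction was downward and not past the threshold, with a median of −0.23 (camera adjusted p = 0.303).

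Dental pulp and follicle mesenchyme had a median of −0.11 (adjusted p = 0.976), with Sox9 at −0.45 (SE 0.20) and Barx1 at 0.65 (SE 0.29). The osteoclast list had 0.29 (adjusted p = 0.154), and its protease gene Ctsk, at 0.66 (SE 0.18), passed adjusted over the list alone, while Mmp9 had 0.61 (SE 0.32). The endothelial list had −0.04 (adjusted p = 0.845; Vwf at −0.41, SE 0.36; Flt1 at −0.26, SE 0.27). The Schwann and nerve list had −0.09 (adjusted p = 0.884; Ngfr at 0.82, SE 0.68). Proliferation genes had a median of −0.01 (adjusted p = 0.658; Plk1 at −0.97, SE 0.35; Mcm4 at −0.57, SE 0.24) and passed, downward, without Gpr115-KO replicate 3 (adjusted p = 0.0291, and 0.745 with an estimated correlation). The unfolded protein response list had a median of −0.005 (adjusted p = 0.819), with the chaperone gene Dnajb9 at 1.09 (SE 0.24), past the threshold adjusted over the list alone, and Edem1 at −0.47 (SE 0.19). Immediate early genes had 0.19 (adjusted p = 0.154), with Junb at 1.06 (SE 0.25) and Jund at 0.98 (SE 0.29) past the threshold adjusted over the list alone. Of the receptor's own family only Adgrf4 and Adgrf5 (0.60, SE 0.34) passed the count filter (adjusted p = 0.230). This list passed, downward, without Gpr115-KO replicate 1 (adjusted p = 0.0365, and 0.482 with an estimated correlation). Adgrf4, the targeted gene, was itself called lower in that fit (−1.45, edgeR adjusted p = 0.0143), so the pass says nothing of the other family members. The 12 measured neighbours of Adgrf4 had a median of −0.09 (adjusted p = 0.675), with the adjacent Cd2ap, encoding a scaffold protein, at −0.59 (SE 0.18). In 5 lists the sign of the median, the mean and the test did not agree, namely the bicarbonate transporters, calcium handling, pulp mesenchyme, keratinizing epithelium and unfolded protein response.

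**Figure D3:**
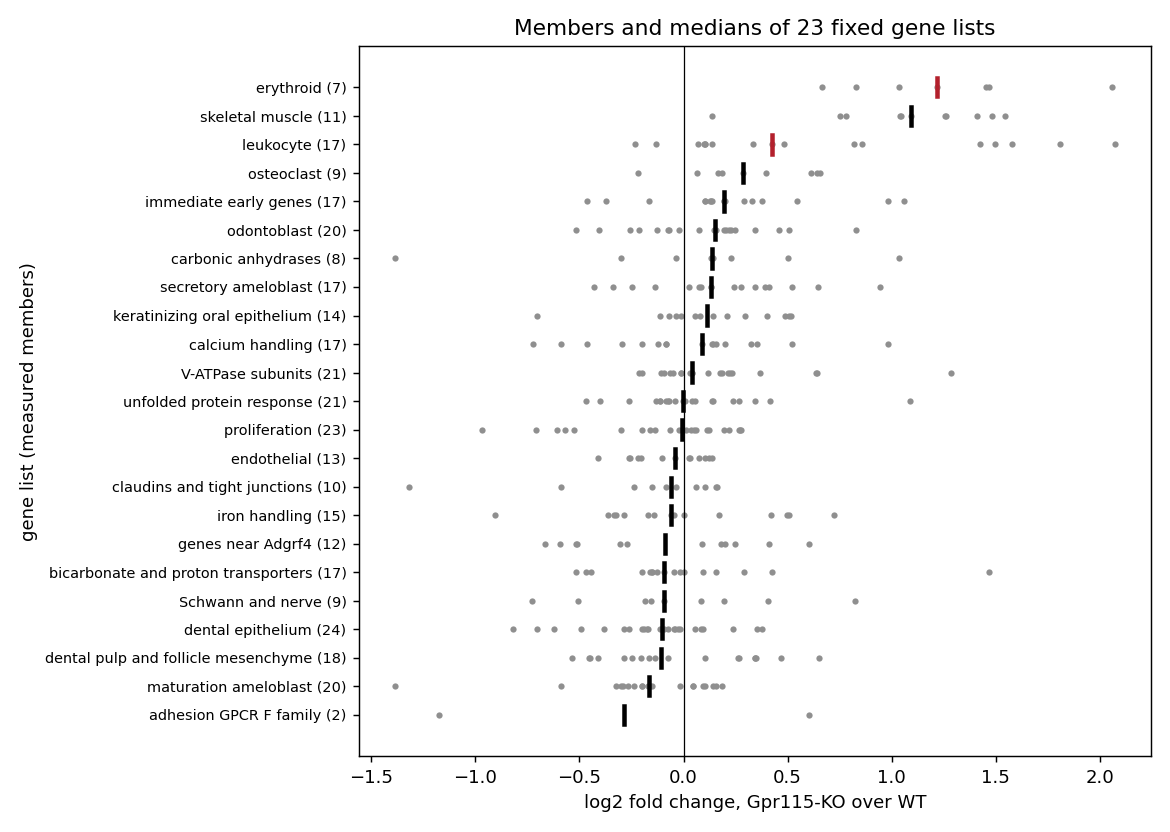
Log2 fold changes (Gpr115-KO over WT) of the measured members of the fixed gene lists, the sex-linked list left out, with a point per gene and a bar at each median, red where the camera adjusted p was under 0.05. The red bars are the erythroid list, with a median of 1.22, and the leukocyte list, with a median of 0.42, and both calls were lost with an estimated correlation (adjusted p = 0.498).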

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

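The chromosome 17, recovered-read and gene length settings, and the estimated correlation with a library left out, were chosen after the data were seen. All 237 alternative fold changes of the 15 called named genes kept their sign, and 202 stayed past the threshold. No fold change or list changed sign where its main or its alternative value was called. The sign of uncalled fold changes or lists changed in 81 alternatives. The count of higher genes was 6 and that of lower genes 18. With no count filter they were 135 and 365, with the DESeq2 Wald test 60 and 177, and at an adjusted p under 0.1 they were 16 and 35. All 24 genes were among those called by each of these settings. On library totals alone 7 were higher and 11 lower. With chromosome 17 left out 0 and 2 remained. This setting kept the p-values of the main fit and adjusted them anew without the genes of chromosome 17, 18 of them called. The p-values of the 6 called genes elsewhere were unchanged, and 4 of these genes lost their calls through the adjustment alone. The reads recovered from the deposited table gave 6 and 18. Leaving out 1 library gave 5 to 10 higher and 7 to 39 lower genes. Whether the replicate numbers pair the samples stays open. Correlations of the same-numbered deviations were 0.27, 0.03 and −0.07, and those of differently numbered libraries ran from −0.19 to 0.15. The replicate block gave 18 higher and 54 lower genes, and Adgrf4 at −1.22 (adjusted p = 0.0254). Adgrf4 was also called with no count filter (−1.18, adjusted p = 7.4e-07) and by DESeq2 (−1.17, adjusted p = 0.000405), over a range of adjusted p from 7.4e-07 to 0.325. Leave-one-out values ran from −1.45 to −0.98 for Adgrf4 and from −3.53 to −0.89 for Car6, whose adjusted p ran from 0.00578 to 0.947 over all alternatives. The list p-values at the preset correlation with 1 library left out ran from 0.0157 to 0.957 for the secretory, 6.4e-06 to 0.957 for the maturation and 0.00594 to 0.931 for the odontoblast list. With an estimated correlation the erythroid and leukocyte lists had adjusted p = 0.498. Without WT replicates 1, 2 and 3 and Gpr115-KO replicates 1, 2 and 3 in turn it was 0.695, 0.781, 0.957, 0.482, 0.865 and 0.378 for the erythroid and 0.695, 0.781, 0.983, 0.149, 0.865 and 0.745 for the leukocyte list. Except where stated, the cause of a change was not tested. Depth limits genes near the count filter, and 3 libraries per group recovered 43.9% of simulated changes of 1 on the log2 scale.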

Other observations

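Apart from the splits of the libraries and the count of chromosome 17 genes with near-identical copies, all tests of this part were chosen after the results were seen. So were the observations on chromosome 19 and on the added gene groups.

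Without Gpr115-KO replicate 1, 11 of the 48 called genes lay on chromosome 19, where 1.5 were expected (518 of 16579 genes tested; two-sided Fisher's exact test across genes, p = 2.0e-07). All 11 were lower. Among them were Rbm4b, Otub1, Prune2, Hhex, Mms19, Pi4k2a, Crtac1, Gm15491, Mgea5 and Tcf7l2, between 4756497 and 55933654. Gm15491 and Mgea5 overlap. Tcf7l2, encoding a transcription factor of Wnt signalling, had 1671, 1307 and 948 CPM in WT and 673, 299 and 368 CPM in Gpr115-KO. With all 6 libraries edgeR called 0 genes on this chromosome, where 15.9% had an unadjusted p under 0.05, and the log2 fold change of Tcf7l2 was −1.55 (adjusted p = 0.129).

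Gene groups added after the data were seen gave list calls that did not outlast an estimated correlation. Of 74 cytosolic ribosomal protein genes 68 had a fitted fold change above 0 (median log2 0.36, camera adjusted p = 7.3e-10, and 0.428 with an estimated correlation). The 17 genes of the mitochondrial genome had a median of 0.45 (adjusted p = 1.7e-05, estimated 0.428) and 84 nuclear genes of respiratory complexes 0.23 (1.2e-05, estimated 0.428). Gpr115-KO replicate 2 stood apart in all 3 groups: the medians of the libraries' deviations were 0.60, 0.66 and 0.39 in it, −0.15 to 0.06 in the other Gpr115-KO libraries and −0.43 to 0.08 in WT. With the gene length trend removed the median log2 fold changes were 0.28, 0.28 and 0.13. The 13 protein-coding H2 genes, with 2 higher and 1 lower past the threshold, had a median of 0.82 (adjusted p = 1.1e-06, estimated 0.0708), a group that leaves out the pseudogene H2-T10, also called lower (−4.91).

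Counts of the Y-linked genes Ddx3y and Uty were 5, 169 and 0 and 5, 76 and 0 in WT, and 0, 1 and 2006 and 0, 0 and 803 in Gpr115-KO. Gpr115-KO replicate 3 thus had the highest Y-linked counts and the lowest Xist (2.93 CPM), a male pattern. WT replicate 2 had Y-linked counts together with Xist at 36.6 CPM. The other libraries had few or no Y-linked counts and Xist at 28.9 to 47.8 CPM, a female pattern. Sex was not even between the libraries and was not a term of the fit, and its effect was not tested.

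Called genes clustered on chromosome 17, over a span much wider than the surroundings of Adgrf4. Reads shared between near-identical copies are argued against as the whole cause, since 22.2% of the 18 called genes there had such a copy. A local effect of the deletion is argued against as the cause of the whole cluster, since all 18 lay farther than 1 Mb from Adgrf4, but an effect on the nearest genes stays open: edgeR called 0 of 6 tested genes within 1 Mb, 33.3% of them had an unadjusted p under 0.05 against 18.7% on the rest of the chromosome (two-sided Fisher's exact test across genes, p = 0.315), and the untested neighbour Ptchd4 had counts of 5, 5 and 6 in WT and 68, 6 and 43 in Gpr115-KO. A candidate explanation, not tested for the 18 genes, is DNA of another strain carried along with the targeted locus, whose differences move reads between copies. The labels give both genotypes as littermates of the C57BL/6 strain. On other chromosomes 4 of 6 called genes had a near-identical copy in the span, against 228 of 15249 tested genes (two-sided Fisher's exact test across genes, p = 7.1e-07). This likeness was noticed before it was tested. Gm10260 and Gm26619 overlap and share the copy Rps18. Counted once, they left 3 of 5 with a copy (two-sided Fisher's exact test across genes, p = 3.2e-05). Both tests cover only genes off chromosome 17, so they cannot decide the cause of the cluster on it. Since 22.2% of the 18 called genes there had such a copy, moved reads would not account for the rest. The tests count only whether a copy exists, not the direction of change, so they cannot tell which way reads would move. The 4 genes with a copy were all lower in Gpr115-KO. Their copies Rps2 (log2 fold change 1.70, SE 0.31) and Rps18 (1.11, SE 0.21) were higher, not past the threshold (edgeR adjusted p = 0.0976 for both). Rps28 stood at 0.37 (SE 0.28). A move of reads alone would leave the sum over all copies level. The sums below hold only the chromosome 17 gene and its called copies. Rps2-ps10 had 31 near-identical copies, Gm10260 and Gm26619 had 6 each and Gm10263 had 7, most of them left out. The sums therefore cannot decide whether reads moved. Rps28 with Gm10263 went from 77.1 ± 29.4 to 79.2 ± 10.3 CPM (SD, n = 3). Rps18 with Gm10260 and Gm26619 went from 107 ± 16.1 to 161 ± 46.5 CPM and Rps2 with Rps2-ps10 from 53.9 ± 8.57 to 128 ± 52.7 CPM. The Rps18 sum adds both Gm10260 and Gm26619, which overlap on opposite strands, so it may hold reads of their shared stretch more than once. No sequence variants were examined.

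Car6 in Gpr115-KO replicate 1 lay near the WT level. A mislabelled WT library is argued against: of the 20 chromosome 17 genes called without this library, it lay nearer the other Gpr115-KO libraries in 19 (95%). The test first covered all 48 called genes, with 29 nearer the other Gpr115-KO libraries, and was then narrowed. Off chromosome 17 the count was 10 of 28. These 28 held the 11 called genes of chromosome 19, and in each of the 11 the library lay nearer WT on log2 CPM. In CPM, with WT at 0 and the other Gpr115-KO libraries at 1, its median position was 0.55 on chromosome 19. On chromosome 17 it was 0.95. Over all genes this library's mean correlation was 0.954 with its own group and 0.962 with WT, and that of Gpr115-KO replicate 3 was likewise 0.955 and 0.958. A less advanced stage of enamel maturation in the Gpr115-KO germs stays open and is not supported by a test: without this library the maturation list without Car6 had a camera p of 0.000136 (0.0252 with an estimated correlation), Klk4 −0.65 (SE 0.20) and Amtn −0.14 (SE 0.18), both not past the threshold, but the library was singled out for a high maturation gene (list median 53.1 CPM in it, 15.3 and 15.7 CPM in Gpr115-KO replicates 2 and 3, and 39.3 to 43.0 CPM in WT), and with all 6 libraries the list was not called (adjusted p = 0.264).

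Erythroid and leukocyte lists were higher in Gpr115-KO, by calls that were both lost with an estimated correlation (adjusted p = 0.498), and the erythroid rise was small in Gpr115-KO replicate 3 (list median 8.96 CPM, against 6.48 to 7.44 CPM in WT). Gene length as the whole cause is argued against for the erythroid list, whose adjusted p was 2.4e-06 with the length trend removed (median 1.22 before, 1.0 after). The leukocyte list kept its call at the preset correlation (adjusted p = 0.000603), but its median went from 0.42 to 0.22 and its lower quartile was 0.05, so length may account for part of it; the rule for both lists was rewritten after a joint form had been seen (81.9% and 50.7% of the medians kept). A lower share of dental tissue, which raises every other cell type alike, stays open for both lists. The erythroid lower quartile of 0.93 lay above the upper quartiles of the endothelial (0.08) and Schwann (0.19) lists. These lists cannot decide it, since whether their cells lie outside the dental tissue was not examined. The skeletal muscle list, not part of this test, had all 11 measured genes above 0 (median 1.09) and was highest in Gpr115-KO replicate 2 (28.0 CPM), like the erythroid list (24.9 CPM). The leukocyte lower quartile of 0.10 lay between the endothelial and Schwann upper quartiles. A difference in blood content or in the genotype itself stays open too.

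Of the 10 splits of the 6 libraries into 3 and 3, the genotypes gave 24 called genes, and 1 split, the real one, gave as many. The highest of the others, with WT replicates 1 and 3 and Gpr115-KO replicate 1 on one side, gave 15, of which 0 were on chromosome 17. With 10 splits a share under 0.05 cannot be reached.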
